A study of Mus musculus with 6 samples.

How the data were processed

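Adipose tissue labelled eWAT was compared between 3 ob/ob and 3 ob/+ samples at 9 weeks of age on 6 two-colour Agilent arrays, 1 per sample. The sample was the Cy5 channel and a pool of ob/+ RNA the Cy3 channel on every array, per the labels, with no dye swap. RNA was extracted with Trizol and amplified before labelling, per the labels' protocols. The arrays were read with Agilent Feature Extraction 8.5.1.1, per the submitters' processing notes. The authors deposited, for each reporter and array, the intensity of both channels on a linear scale, already normalized by a method not given in the sources used here. Per the values, 97.45% of the intensities come in steps of 0.01, and the median log2 ratio of every array was 0. The deposited p-value of each reporter and array compares its 2 channels, by a test not given in the sources used here, and was used only as described in the closing section. The deposited log10 ratios of the series matrix equal the ratio of the 2 intensities within 0.02 on the log2 scale at 100% of the reporters of the matching column. The background correction and error model are not given in the sources used here.

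The deposited table calls the controls and their pool wt, where the labels give ob/+. The series' design text speaks of islets and db/db, where the title, labels and table name adipose tissue and ob/ob. The labels were followed in both cases. The table numbers its columns by sample numbers that differ from the replicate numbers of the labels, so table columns were assigned to groups only. Analyses that need the replicate number used the series matrix. All columns of per-sample values were assigned, leaving 0 unassigned. Gene symbols were taken from the deposited table and updated through a reference gene table, which changed the symbol of 3197 reporters. In all, 30173 of 39507 reporters had a symbol and 9334 had none. Values were missing on 1 or more arrays for 281 reporters, whose median mean intensity was 6.38 against 0.13 for all reporters. The 100 reporters with values on fewer than 2 arrays of a group were not tested, and their median mean intensity was 39.5.

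For each reporter, log2 of the sample over the pool intensity was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default prior), as ob/ob minus ob/+, two-sided. P-values were adjusted by the Benjamini-Hochberg method over reporters, at a threshold of 0.05. A shared dye or reference effect cancels in this difference. A gene was represented by its brightest reporter, and 41 genes had called reporters in both directions. The spread estimate borrowed little between reporters (prior degrees of freedom 0.86), and 1514 reporters had no residual spread. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 38 lists, each with at least 5 measured members. The lists, the tests and most alternatives were fixed before the data were examined.

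The text names genes by a rule fixed at the same time. It takes Lep, the 12 largest rises and 12 largest falls among called genes whose arrays do not overlap, up to 4 members of each list with the lowest p, and 33 fixed genes. The text gives examples from the list members, and 1 of the fixed genes is not reported here. On simulated data with 200 changed reporters, 57 of 66 reporters changed 4-fold were recovered, 36 of 67 changed 2-fold and 16 of 67 changed 1.5-fold, with 103 false calls, of which 1 was at a mean intensity above 0.1. In a simulation with the effects of the real calls, all other reporters unchanged and the spread set by brightness alone, 5.4% of calls were of unchanged reporters. Alternatives were other normalizations, the sample channel alone, filters on dim reporters, other priors, array weights, a replicate block, leaving out each array, other rules for genes with several reporters, other thresholds and other list tests. A filter at a mean intensity of 0.1 was added after the rounding was seen. Python 3.11.15 and matplotlib 3.10.9 drew the figures.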

Results

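Transcript levels were measured on 6 two-colour arrays of adipose tissue, labelled eWAT, from mice 9 weeks old. The tissue came from 3 ob/ob samples and 3 ob/+ samples. Mice of the ob/ob genotype carry the obese mutation of Lep on both chromosomes, lack working leptin and become obese, and ob/+ mice are the lean controls. Each array compared 1 sample, labelled with Cy5, with a pool of ob/+ RNA, labelled with Cy3. The deposited table held 39507 reporters, of which 39407 could be tested, and these covered 25753 gene symbols. Median intensity of the sample channel ranged from 0.11 to 0.15 between arrays in the authors' units, and 42.0% of all intensities lay under 0.1, where the step of 0.01 in which 97.45% of the intensities were given is coarse. The number of arrays limits the precision of every value. The deposited table calls the controls and the pool wt, and the genotype ob/+ is that of the labels. The labels and the table number the samples without saying that each came from its own animal, so p-values measure the spread between these samples.

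The comparison of obese with lean tissue asked which transcripts differ with the ob/ob genotype. Most measured members of the macrophage, lysosomal, inflammatory, cholesterol synthesis and cell cycle lists were higher in ob/ob, and most of the branched chain amino acid breakdown list were lower. Of 25753 genes, 3203 were higher and 3125 lower in ob/ob at an adjusted p under 0.05 in limma, and 916 rose and 992 fell at least 2-fold. Over reporters the counts were 4202 higher and 4023 lower of 39407. In 39.7% of the genes the 3 ob/ob arrays lay wholly on one side of the 3 ob/+ arrays, against 10% by chance. The gene count of 6328 was 3289 without ob/+ replicate 1, 3525 without ob/+ replicate 3, 4042 without ob/ob replicate 2 and 3134 without ob/ob replicate 3, and 556 after quantile normalization of the log ratios. After that normalization 109 of the 149 called named genes other than Lep no longer passed, and 40 still passed. Before it, the ob/+ ratios to the ob/+ pool had SDs of 0.21 to 0.23 across reporters, against 0.57 to 0.63 for ob/ob. Giving all arrays 1 distribution widens the former and narrows the latter, so lost calls and smaller changes follow in part from the method. Simulated data took the real calls as true changes, left all other reporters unchanged and set the spread by brightness alone. There 21% of the calls at a mean intensity of 0.1 or less were of unchanged reporters, against 1.7% of the brighter calls. These shares need not hold for the real calls.

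Replicates were close. The log2 ratios of the ob/ob arrays correlated at r = 0.83 to 0.89 across reporters, which are not independent replicates. The ob/+ arrays, each set against a pool of ob/+ RNA, correlated at r = -0.308 to 0.065. Both channels and dyes are given in the labels, and deviations from a shared mean oppose each other by construction, so the direction of the ratios was kept. The median SD of a reporter's log2 ratio was 0.112 in ob/+ and 0.128 in ob/ob. In limma 0 reporters had a mean ratio in the ob/+ arrays that departed from 0 at an adjusted p under 0.05. At an unadjusted p under 0.05, 536 did. If the pool was made of these samples, differences between them cancel in this mean. The count then bears on dye or pooling effects only, not on how close the replicates were.

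Lep, the gene that carries the obese mutation and encodes the satiety hormone leptin, was 4.33-fold higher in ob/ob (log2 fold change 2.12 ± 0.08, SE, n = 3 per group, limma adjusted p = 0.000839). The mutation changes the protein and leaves a transcript, so this level does not test the labels. Its ob/+ intensity was low, at 0.107 ± 0.006 (SD), against 0.433 ± 0.045 in ob/ob. Rounding alone can move its log2 fold change by 0.22 or more. Several other adipocyte transcripts fell. Nnat, which encodes neuronatin, fell by 4.36 ± 0.30 on the log2 scale (SE), with values on 2 ob/+ and 3 ob/ob arrays, and Acvr1c, an activin receptor of adipocytes, fell by 1.82 ± 0.16. Adipoq, which encodes adiponectin, fell by 1.26 ± 0.22, Retn, which encodes resistin, fell by 1.70 ± 0.38, and Slc2a4, the insulin-responsive glucose transporter, fell by 0.86 ± 0.21. Tmem182 rose 2.83-fold, and Mest, an imprinted gene linked to fat expansion, rose by 1.80 ± 0.23. Npr3, the natriuretic peptide clearance receptor, rose by 0.89 ± 0.20. Pparg, the master regulator of adipocyte formation, had a log2 fold change of 0.07 ± 0.12 (adjusted p = 0.704), and Sfrp5 and Hsd11b1 had 0.02 ± 0.05 and 0.32 ± 0.37, also past no threshold.

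Of 16 measured mature adipocyte markers and adipokines, 8 were lower, 2 were higher and 6 did not pass the test, with the same counts adjusted over the list alone. The list had a camera adjusted p = 0.0437, and an adjusted p = 0.734 with an estimated correlation. Its call was lost without ob/+ replicate 1 (adjusted p = 0.0574), ob/+ replicate 2 (0.066), ob/ob replicate 2 (0.0738) or ob/ob replicate 3 (0.0608), where the mean log2 fold change of the list was -0.57 to -0.68, against -0.74 on all arrays. It was also lost without dim reporters (0.0638 to 0.155), and the cause was not tested. The mean was -0.74 without the lowest quartile and -0.64 without reporters below the median, which removes its member Adrb3 (mean intensity 0.1158). None of its members had a mean intensity of 0.1 or less. Cfd, which encodes the adipokine adipsin, and Pck1, the first enzyme of glyceroneogenesis, had values on the 3 ob/ob arrays only and were not tested. There their mean log2 ratios to the ob/+ pool were -3.02 ± 0.20 and -1.69 ± 0.66 (SD, n = 3). Leaving out 1 array ended some calls. Those of Adipoq (adjusted p up to 0.07) and Retn (up to 0.127) were lost without any array but ob/ob replicate 1, and those of Slc2a4 (up to 0.142) likewise. That of Npr3 (up to 0.109) was lost without any 1 of the 6.

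**Figure D1:**
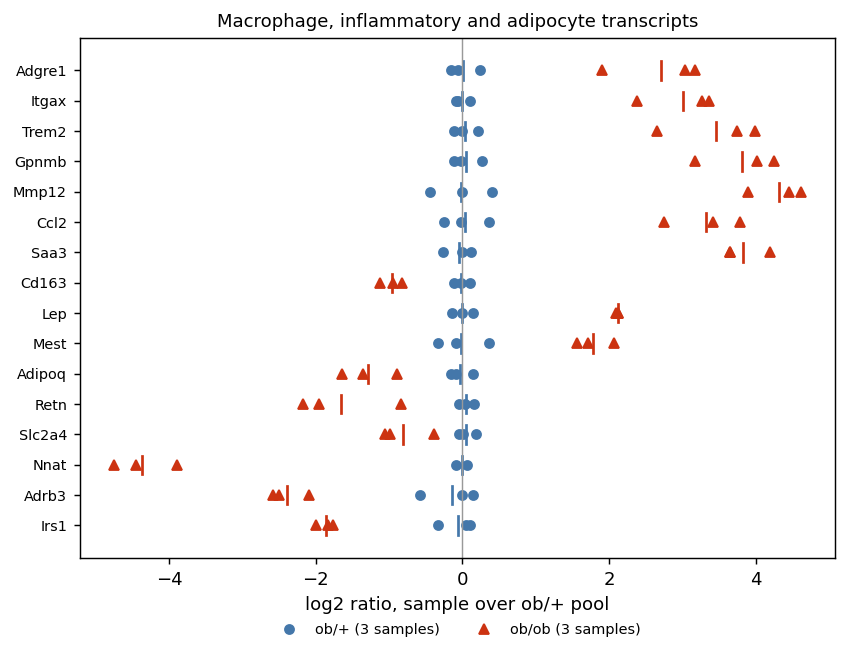
Log2 ratio of sample over ob/+ pool for 16 named transcripts, 1 point per array and a bar at the mean of each group of 3. Gpnmb, Trem2, Itgax, Mmp12, Ccl2 and Saa3 lie above all ob/+ arrays on the 3 ob/ob arrays, and Cd163 and Adipoq lie below them.

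Macrophage transcripts were among the largest rises. Mmp12, a macrophage elastase, rose 20.2-fold (log2 4.34 ± 0.30, SE), Gpnmb, a marker of lipid-laden macrophages, 13.7-fold (3.77 ± 0.32), and Trem2, a lipid-sensing receptor of macrophages, 10.8-fold (3.43 ± 0.39). Itgax, which encodes CD11c, rose 8.03-fold (3.01 ± 0.29) and Adgre1, a surface marker of mature macrophages, 6.50-fold (2.70 ± 0.38). Cd68, a lysosomal glycoprotein of macrophages, rose by 0.78 ± 0.16 and Spp1, which encodes osteopontin, by 2.20 ± 0.42. Cd163, a scavenger receptor of resident macrophages, fell by 0.95 ± 0.10. Of 20 measured macrophage markers, 16 were higher, 1 was lower and 3 did not pass, or 17 and 1 adjusted over the list alone (camera adjusted p = 8.05e-07, and adjusted p = 0.575 with an estimated correlation). Among them were Lyz2 (log2 2.16 ± 0.13) and C1qa (0.72 ± 0.06). Of 17 lipid-loaded macrophage markers, 16 were higher and none was lower, also adjusted over the list alone (camera adjusted p = 2.87e-09, and adjusted p = 0.51 with an estimated correlation). These included Fabp5 (2.00 ± 0.10) and the protease Ctsd (1.77 ± 0.13). The call of Adgre1 was lost without ob/+ replicate 1 or 3 or ob/ob replicate 3 (adjusted p up to 0.0543), and those of Cd68 and Spp1 without any array but ob/ob replicate 1 (up to 0.105 and 0.0941).

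Most lysosome and inflammation genes were higher too. Of 23 lysosome genes, 20 were higher and none was lower, or 21 adjusted over the list alone (camera adjusted p = 1.89e-09, and adjusted p = 0.575 with an estimated correlation). Among them were the proton pump subunits Atp6v1a (log2 1.46 ± 0.02, SE) and Atp6v1b2 (1.32 ± 0.12). Atp6v1a was dim at an ob/+ intensity of 0.087, where rounding alone can move it by 0.26 or more, far beyond its SE. Of 26 cytokines, chemokines and acute phase genes, 20 were higher and 1 was lower, or 22 and 1 adjusted over the list alone (camera adjusted p = 7.95e-08, and adjusted p = 0.575 with an estimated correlation). Saa3, an acute phase protein, rose by 3.88 ± 0.20, Ccl2, a monocyte attractant, by 3.29 ± 0.32, and Ccl8 by 1.89 ± 0.16. The dim Ccl3 rose by 3.23 ± 0.24 from an ob/+ intensity of 0.023, where rounding alone can move it by 0.94 or more. Il6, also dim at an ob/+ intensity of 0.043, rose by 0.74 ± 0.12, where rounding can move it by 0.64 or more. Lcn2 rose by 0.62 ± 0.15. Tnf, by contrast, had a log2 fold change of -0.01 ± 0.04 (adjusted p = 0.881). Of 12 genes of antigen presentation by MHC class II, 4 were higher and 1 was lower, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.0139, and adjusted p = 0.661 with an estimated correlation), with Ctss at 2.78 ± 0.29. That list's call was lost without ob/ob replicate 2 (adjusted p = 0.0536), where its mean log2 fold change of 0.58 was 0.50. The call of Lcn2 was lost without any array but ob/ob replicate 1 (adjusted p up to 0.153). That of Il6 was lost without ob/+ replicate 1 or 3 or ob/ob replicate 2 or 3 (up to 0.0673).

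Of 20 measured interferon response genes, 4 were lower and none was higher, also adjusted over the list alone (camera adjusted p = 0.0378, and adjusted p = 0.646 with an estimated correlation). Irf7, a regulator of interferon genes, fell by 1.01 ± 0.10 on the log2 scale (SE). The list's call was lost without ob/+ replicate 1 (adjusted p = 0.0671), ob/ob replicate 1 (0.0866) or ob/ob replicate 3 (0.0852), and without dim reporters (0.0638 to 0.132), after quantile normalization (0.0922) or with the sample channel alone (0.0869). The mean log2 fold change of the list was -0.25, and it was -0.21 to -0.22 without those arrays, -0.25 to -0.26 without dim reporters, -0.17 after quantile normalization and -0.24 with the sample channel alone.

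Most cholesterol synthesis genes rose. Of 17 measured genes, 14 were higher and 1 was lower, also adjusted over the list alone (camera adjusted p = 1.88e-07, and adjusted p = 0.575 with an estimated correlation). Dhcr7, which makes cholesterol from its last precursor, rose by 2.78 ± 0.12 on the log2 scale (SE), Insig1, the sterol-regulated retention protein, by 2.36 ± 0.14 and Lss by 1.76 ± 0.11. Of 18 de novo lipogenesis genes, 5 were higher and none was lower, also adjusted over the list alone (camera adjusted p = 0.0439, and adjusted p = 0.734 with an estimated correlation). The pentose phosphate enzyme Pgd rose by 1.52 ± 0.19. Fasn, the fatty acid synthase, had a log2 fold change of 0.71 ± 0.28 (adjusted p = 0.166), Scd1 -0.02 ± 0.33 and Pnpla3 0.50 ± 0.24, and none of these passed. The call of the lipogenesis list was lost without ob/+ replicate 3 (adjusted p = 0.114) or ob/ob replicate 1 (0.158), and with array weights (0.0994), where its mean log2 fold change of 0.50 was 0.42, 0.30 and 0.39.

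Of 19 genes of branched chain amino acid breakdown, 12 were lower and none was higher, or 16 lower adjusted over the list alone (camera adjusted p = 8.05e-07, and adjusted p = 0.589 with an estimated correlation). Mccc1 fell by 1.14 ± 0.11 on the log2 scale (SE) and Ppm1k, the phosphatase that activates the pathway, by 1.15 ± 0.11. Of 17 insulin signalling genes, 7 were lower and 1 was higher, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.0437, and adjusted p = 0.646 with an estimated correlation). Irs1 fell by 1.81 ± 0.14, Irs2 by 1.07 ± 0.14 and Insr, the insulin receptor, by 0.97 ± 0.15. The list's call was lost without ob/+ replicate 1 (adjusted p = 0.141), ob/ob replicate 2 (0.0738) or ob/ob replicate 3 (0.0614), where its mean log2 fold change was -0.39 to -0.43, against -0.44 on all arrays, and with camera on ranks (0.0534). It was also lost without dim reporters (0.0638 to 0.0848), where its mean was -0.44 to -0.46. None of its members had a mean intensity of 0.1 or less, and the cause was not tested. The call of Insr was lost without ob/+ replicate 3 (adjusted p = 0.0542), and the dimmest reporters of Insr and Irs1 had log2 fold changes of 0.24 (adjusted p = 0.0601) and -0.10 (adjusted p = 0.259).

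Other metabolic lists passed no threshold. Of 12 triglyceride synthesis genes, 2 were higher and 3 lower, or 3 and 4 adjusted over the list alone, with Mogat1 at -1.99 ± 0.06 (log2, SE) and Mogat2 at 1.40 ± 0.14 (camera adjusted p = 0.614). Mogat2 had an ob/+ intensity of 0.09, where rounding alone can move it by 0.28 or more. Of 13 lipolysis and lipid droplet genes, 1 was higher and 2 were lower, also adjusted over the list alone, and Adrb3, the adipocyte beta receptor, fell by 2.24 ± 0.25 (camera adjusted p = 0.161, or 0.0377 without ob/+ replicate 3). Of 17 fatty acid oxidation genes, 2 were higher and 1 was lower, also adjusted over the list alone (camera adjusted p = 0.929). Of 21 mitochondrial genes, 6 were lower and none was higher, or 11 and 3 adjusted over the list alone (camera adjusted p = 0.0548). This list passed without ob/ob replicate 1 (0.00533), with array weights (0.0369) and with the sample channel alone (0.0363). Of 14 thermogenic genes, 5 were higher and 1 was lower, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.0784, or 0.0286 after quantile normalization). Otop1, with an ob/+ intensity of 0.063, rose by 3.80 ± 0.17 and Kcnk3 by 0.78 ± 0.06. Rounding alone can move Otop1 and Adrb3 by 0.33 or more each. Ppargc1a, a coactivator of mitochondrial genes, fell by 2.07 ± 0.18, while its dimmest reporter did not pass (-0.38, adjusted p = 0.0964), and Ucp1, the uncoupling protein, had 0.11 ± 0.10 (adjusted p = 0.5).

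The largest rises were of mixed kinds. Itgad, an integrin of macrophages, rose 50.1-fold (log2 5.65 ± 0.48, SE) from an ob/+ intensity of 0.037, Pvalb, which encodes parvalbumin, 24.0-fold (4.58 ± 0.15) from 0.05, Ubd 19.8-fold (4.31 ± 0.25) and S100a8 19.8-fold (4.30 ± 0.26). Ncan rose 18.3-fold (4.19 ± 0.27) and Vsig8 15.5-fold (3.95 ± 0.31). Tph2, Olr1, AU067648, Tfr2 and Ppp1r3a rose 18.4-fold to 26.4-fold, with ob/+ intensities of 0.00764 to 0.03, close to the step of 0.01. Rounding alone can move the log2 fold change by at least 0.51 for Itgad, 0.37 for Pvalb and 0.76 to 1.24 for Tph2, Olr1, Tfr2 and Ppp1r3a. The sizes of these rises and their order are therefore imprecise. The dimmer of 2 reporters of Itgad (log2 0.06, adjusted p = 0.505) and the dimmest of 3 of Ncan (-0.20, adjusted p = 0.366) did not pass. After quantile normalization 3 of the 12 largest rises no longer passed. Ncan was then 8.06-fold higher (adjusted p = 0.0591), Olr1 8.96-fold, against 26.1-fold before (0.0594), and AU067648 8.29-fold, against 20.1-fold (0.0545).

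The largest falls included genes known from epithelium. Crisp1, a secreted protein of the epididymis, fell by 7.07 ± 0.61 on the log2 scale (SE), from an intensity of 12.99 in ob/+ to 0.073 in ob/ob, and Crisp3 fell by 6.72 ± 0.60. Dnah9, a motor protein of motile cilia, fell by 6.64 ± 0.64, Dcdc2a by 6.02 ± 0.35, and Foxj1, the regulator of motile cilia, by 4.72 ± 0.30. Cdh16, an epithelial cadherin, fell by 5.14 ± 0.36, Adgrg2, a receptor of the efferent ducts, by 4.91 ± 0.31, and Mmp7, a protease of epithelia, by 5.55 ± 0.25. Cuzd1 fell by 5.98 ± 1.21, Bex1 by 5.30 ± 0.42 and Prr15l by 4.69 ± 0.25. Car3, an abundant carbonic anhydrase of adipocytes, fell by 5.62 ± 0.37. The ob/ob intensity was 0.00365 ± 0.00312 (SD) for Dnah9, under the step of 0.01, and it was 0.04 for Cdh16, 0.043 for Prr15l and 0.05 for Mmp7 and Dcdc2a, so the sizes of these falls and their order are imprecise. Within the ob/+ arrays the log2 ratio of Crisp1 ranged from -1.40 to 0.91, and that of Cuzd1 from -2.92 to 1.46. The call of Cuzd1 was lost without ob/+ replicate 3 or any 1 ob/ob array (adjusted p up to 0.104). After quantile normalization 10 of the 12 largest falls no longer passed (adjusted p = 0.0525 to 0.383), all but Car3 and Mmp7, and Crisp1 then had a log2 fold change of -5.61 (adjusted p = 0.0794).

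**Figure D2:**
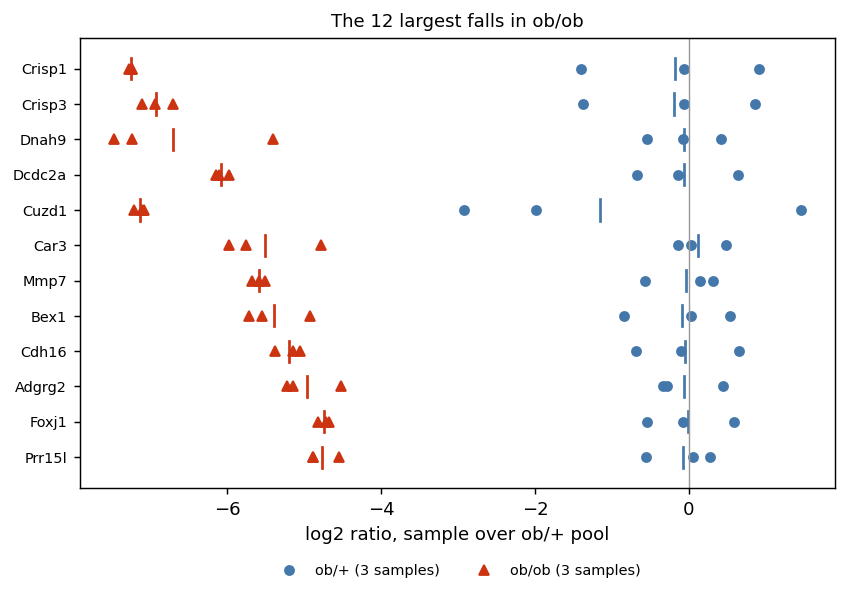
Log2 ratio of sample over ob/+ pool for the 12 largest falls, 1 point per array and a bar at the mean of each group of 3. The ob/ob arrays lie below all ob/+ arrays for each gene, and the ob/+ arrays spread from -2.92 to 1.46 for Cuzd1.

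Markers of other cell types were measured in the same way. Of 12 mesothelial markers, 5 were lower, or 6 adjusted over the list alone (camera adjusted p = 0.000239, and adjusted p = 0.603 with an estimated correlation). Krt8 fell by 2.94 ± 0.27 on the log2 scale (SE), Krt18 by 3.22 ± 0.34 and Wt1 by 1.40 ± 0.18. Of 20 epididymis and seminal vesicle markers, 2 were lower and none was higher, also adjusted over the list alone (camera adjusted p = 0.0439, and adjusted p = 0.575 with an estimated correlation). Its call was lost without ob/+ replicate 3 (adjusted p = 0.153), ob/ob replicate 1 (0.151) or ob/ob replicate 2 (0.0704), without dim reporters (0.0799 to 0.155), after quantile normalization (0.291), with a trended and robust prior (0.0668) and with array weights (0.0813). The mean log2 fold change of this list was -0.99. It was -0.96 to -1.002 without those arrays, -1.20 to -1.60 without dim reporters, which removed members, -0.47 after quantile normalization, -0.99 with the other prior and -0.90 with array weights. Of 16 progenitor and fibroblast markers, 3 were higher and 8 lower, or 4 and 8 adjusted over the list alone (camera adjusted p = 0.106), with Pdgfra at -0.84 ± 0.08 and Lum at 0.94 ± 0.11. Of 16 endothelial markers, 1 was lower, also adjusted over the list alone (camera adjusted p = 0.213, or 0.0387 without ob/ob replicate 1).

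Lists of other immune cells and tissues passed no threshold. T cell markers had 2 higher of 17, also adjusted over the list alone (camera adjusted p = 0.308). B cell and plasma cell markers had 2 higher of 13, or 1 adjusted over the list alone (camera adjusted p = 0.122, or 0.00893 without ob/ob replicate 1). Mast cell markers had 3 lower of 10, also adjusted over the list alone (camera adjusted p = 0.119). Neutrophil markers had 1 higher and 1 lower of 11, or 2 and 3 adjusted over the list alone (camera adjusted p = 0.911). Skeletal muscle markers had 2 higher and 2 lower of 13, also adjusted over the list alone (camera adjusted p = 0.696), and pancreatic islet markers 3 higher of 16, or 4 adjusted over the list alone (camera adjusted p = 0.286). Pancreatic acinar markers had 1 higher and 1 lower of 11, or 1 and 2 adjusted over the list alone (camera adjusted p = 0.294), and erythroid markers 0 of 8 on both counts, adjusted over the list alone too (camera adjusted p = 0.865). For neutrophil and acinar markers the mean log2 fold changes were 0.07 and 0.10, while the medians were -0.01 and -0.15 and the test pointed down.

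Of 24 collagens and matrix genes, 9 were higher and 2 lower, or 12 and 3 adjusted over the list alone (camera adjusted p = 0.0234, and adjusted p = 0.51 with an estimated correlation). Lox, a collagen crosslinking enzyme, rose by 2.07 ± 0.13 on the log2 scale (SE) and Timp1 by 1.83 ± 0.17, and Col6a3 had 0.41 ± 0.12 (adjusted p = 0.0744). The list's call was lost without ob/ob replicate 2 (adjusted p = 0.07) and after quantile normalization (0.0656), where its mean log2 fold change of 0.38 was 0.36 and 0.23. Of 19 cell cycle genes, 18 were higher and none was lower, also adjusted over the list alone (camera adjusted p = 2.87e-09, and adjusted p = 0.575 with an estimated correlation). Birc5 rose by 1.86 ± 0.19 and Cdk1, the mitotic kinase, by 1.00 ± 0.11. Of 15 oxidative stress and NADPH oxidase genes, 9 were higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.0139, and adjusted p = 0.51 with an estimated correlation). Sod2 rose by 1.57 ± 0.13, Gsta4 fell by 2.43 ± 0.22 and Gpx3 fell by 1.80 ± 0.10. That list's call was lost without ob/+ replicate 1 (adjusted p = 0.0574) or ob/+ replicate 3 (0.0647), where its mean log2 fold change of 0.42 was 0.42 and 0.43.

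The remaining lists passed no threshold. Of 16 clock genes, 4 were higher and 3 lower, or 4 and 6 adjusted over the list alone (camera adjusted p = 0.213). Per3 fell by 1.56 ± 0.18 on the log2 scale (SE) and Dbp by 1.44 ± 0.20, while Bmal1 rose by 1.08 ± 0.18. The dimmest reporter of Per3 did not pass (-0.31, adjusted p = 0.359). The call of Dbp was lost without ob/ob replicate 3 (adjusted p = 0.0502), and that of Bmal1, whose symbol here is Arntl, without any ob/+ array or ob/ob replicate 3 (up to 0.0718). Hypoxia genes had 2 higher and 3 lower of 14, also adjusted over the list alone (camera adjusted p = 0.432), with Ndrg1 at -1.54 ± 0.11 and Ldha at 0.96 ± 0.14, whose call was lost without ob/+ replicate 1 or 3 (adjusted p up to 0.0585). Endoplasmic reticulum stress genes had 3 higher and 2 lower of 15, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.911), with Asns at -1.45 ± 0.15, Atf3 at 2.38 ± 0.40 and Ddit3 at 0.90 ± 0.17. The call of Atf3 was lost without any array but ob/ob replicate 1 (adjusted p up to 0.0695), and that of Ddit3 without ob/+ replicate 1 or 3 or ob/ob replicate 2 or 3 (up to 0.0869). Glucocorticoid response genes had 2 higher of 14, or 1 adjusted over the list alone (camera adjusted p = 0.911). Immediate early genes had 2 higher of 15, also adjusted over the list alone (camera adjusted p = 0.933), with Egr2 at 2.20 ± 0.24 and Atf3 again among them. Ribosomal protein genes had 1 higher and 1 lower of 17, or 0 and 0 adjusted over the list alone (camera adjusted p = 0.286). Sex-linked transcripts had 1 lower of 6, also adjusted over the list alone (camera adjusted p = 0.626). For immediate early and sex-linked transcripts the means were 0.17 and -0.16, the medians -0.04 and 0.01, and the test pointed down.

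The 40 named genes that still passed after quantile normalization included 9 of the largest rises, Itgad, Tph2, Pvalb, Mmp12, Ubd, S100a8, Tfr2, Ppp1r3a and Vsig8. Others were Gpnmb, Trem2, Itgax, Adgre1, Lyz2, Msr1, Ctss, Atp6v1a, Saa3 and Ccl3. The rest were Dhcr7, Lss, Mccc1, Mogat1, Pde3b, Cpt1b, Otop1, Kcnk3, Acvr1c, Nnat, Car3, Mmp7, Pdgfra, Lox, Timp1, Gpx3, Gsta4, Actn3, Birc5, Cdk1 and Ccnb1. All 149 kept their direction with a smaller change, which the normalization itself brings in part. The fold of 26 of these 40 moved by over 1.5 times. Itgad was then 18.1-fold higher, Mmp12 8.81-fold, Gpnmb 5.95-fold, Trem2 5.11-fold, Itgax 4.28-fold and Adgre1 3.67-fold.

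In all, 16 of 38 lists were called with the preset correlation and 0 with an estimated one, where 3 passed an unadjusted p under 0.05. That correlation was estimated from the same 6 arrays, so the estimate is itself imprecise. The calls thus depend on the correlation used, and the list tests carry little weight. Of the other splits of the 6 arrays, 1 called 24 lists. Every other split mixes the genotypes and keeps part of their difference, so it cannot show how many lists chance would call. The counts of members are limited too, since members of a list can move together (estimated correlation -0.06 for neutrophil markers to 0.787 for the cell cycle). They stand against 24.6% of all genes called, or 40.4% of the genes with a mean intensity above 0.1 fitted alone. The fry test, which does not compare a list with other genes, ended the calls of the mature adipocyte (adjusted p = 0.453) and lipogenesis (0.147) lists. It passed the triglyceride synthesis, thermogenic and skeletal muscle lists (0.00653 each) and the mast cell list (0.00199).

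**Figure D3:**
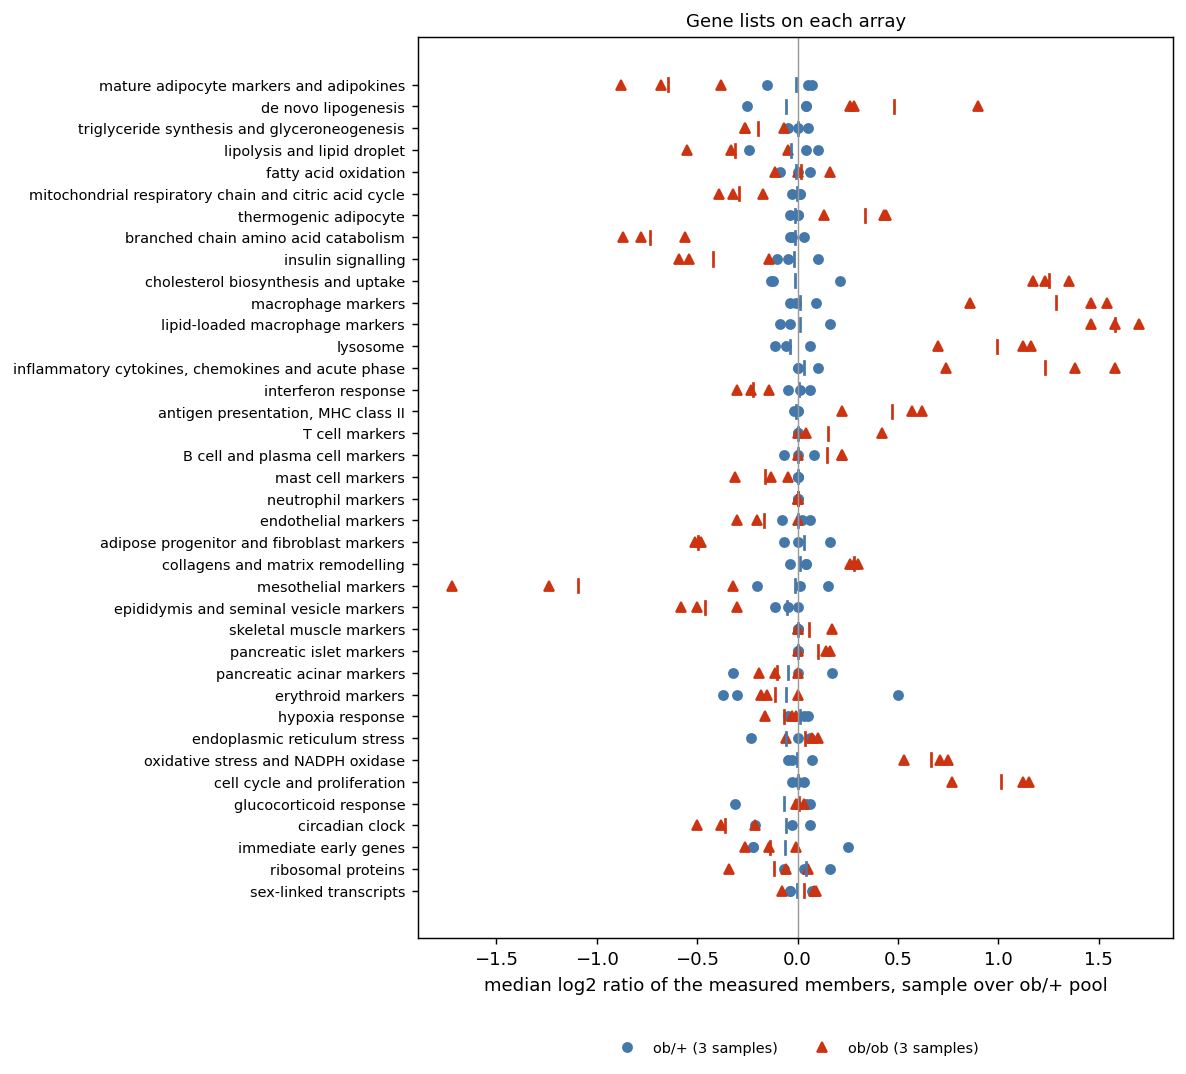
Median log2 ratio of sample over ob/+ pool of each list's measured members, 1 point per array and a bar at the mean of each group of 3. Macrophage markers lie at 0.86 to 1.54 on the ob/ob arrays, and mesothelial markers at -1.72 to -0.32.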

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

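The authors' deposited p-values for single arrays, which the comparison did not use, fell under 0.01 for 5862, 6654 and 6620 reporters on the 3 ob/ob arrays. On the 3 ob/+ arrays they did so for 312, 478 and 483 reporters. The counts were looked at because they lie in a column outside the main measurement and exceed those of the control arrays.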

How the results depend on the processing

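The filter at a mean intensity above 0.1 was chosen after the data were seen. The median log2 ratio of every array was already 0, so median centring tests nothing here. The series matrix gave 6329 genes. The log2 fold change of Lep was 2.05 to 2.18 without single arrays and 1.54 (adjusted p = 0.0269) after quantile normalization. Quantile normalization of log ratios, which raised the median SD of ob/+ ratios from 0.112 to 0.223 and lowered that of ob/ob ratios from 0.128 to 0.085 by giving all arrays 1 distribution, left 750 reporters (432 higher, 318 lower) and 556 genes (310 and 246, of which 127 and 87 at least 2-fold). Of those 556 genes, 555 were called in the reported fit. Without single arrays the ranges were 4124 to 6960 reporters (1999 to 3775 higher, 1929 to 3486 lower), 3134 to 5364 genes (1523 to 2873 higher, 1521 to 2619 lower), 542 to 977 genes at least 2-fold higher and 646 to 987 lower, and 3 to 6 lists lower. Fewer samples entered these fits. The replicate block gave 3290 reporters (1672 higher, 1618 lower), 2580 genes (1284 and 1296) and 465 and 596 at least 2-fold. Deviations of equally numbered samples correlated at r = 0.062, -0.062 and 0.003, and not every sample correlated best with its own number. The values gave no sign that the numbers pair the samples, but such a check cannot exclude it. Stricter thresholds gave 2693 reporters at an adjusted p under 0.01 (1328 higher, 1365 lower), 4724 at 1.5-fold (2342, 2382) and 2299 at 2-fold (1103, 1196). The ob/ob arrays against the pool, with the spread of all 6 arrays but without the error of the ob/+ mean, gave 12811 (6567, 6244). With an estimated inter-gene correlation 0 lists were called, 0 higher and 0 lower. Without the lowest quartile, without reporters below the median, and with a mean intensity above 0.1, 2 lists were lower each time, and the cause was not tested. The spread of ob/ob ratios was 0.114 in the brighter reporters. The dimmest reporter of a gene turned the sign of Ncan (-0.195), Insr (0.239) and Egln3 (0.084), which come from other probes. No background values or slide and scan batches were in the columns used here, so those alternatives were not run. In the simulation with the effects of the real calls, 58.8% of the changed reporters with a mean intensity of 0.1 or less were called, against 78.6% of the brighter ones.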

Other observations

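Some epididymal transcripts differed between the ob/+ samples. The genes named here were chosen after their values were seen. Across all 20 epididymis and seminal vesicle markers, 11 of them dim, the median log2 ratios were close, at -0.11, -0.05 and 0 in ob/+ replicates 1, 2 and 3. The log2 ratios to the pool for Adam7 were -3.12, 1.46 and -2.54 in ob/+ replicates 1, 2 and 3, and those of Spint3 were -3.79, 1.62 and -3.95. Lcn5 was highest in replicate 1 (1.25, against -2.00 and -1.42), while Gpx5 (1.1) and Lcn9 (1.38) were highest in replicate 3. In the ob/ob samples Adam7 lay between -3.99 and -3.62 and Spint3 between -4.35 and -4.22. Neither passed the test between the groups (adjusted p = 0.27 and 0.426).

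The tests of the epithelial, macrophage and dim-reporter patterns were chosen after the results were seen. The fall of epithelial transcripts may come from duct epithelium carried in the ob/+ samples and their pool. Of 36 epithelial junction, keratin and motile cilia genes with a mean intensity above 0.1, 63.9% were lower in ob/ob, where such cells should bring all their abundant transcripts, and so were 60.5% of all 43 measured, or 57.5% of those not among the largest falls. Epcam fell by 4.06 on the log2 scale, Cdh1 fell by 4.23 and Rsph1 fell by 2.93, but St14 rose by 1.51 (adjusted p = 0.0086), Hydin (0.16) and Spag17 (0.07) did not pass, Krt8, Krt18 and Krt19 are mesothelial markers too, and Cdh16, Dnah9 and Foxj1 are among the largest falls that raised the question. Fewer mesothelial cells alone stay open, since the 13 motile cilia genes above that intensity had a median of -1.69, with a standard error of the mean of 0.61, which did not clear the bound set for it, and all 18 measured had -0.56. A change of these tissues with the genotype was not tested and stays open.

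The rise of macrophage transcripts is weighed against a lower share of adipocytes, which would raise other cell types alike. Macrophage markers exceeded endothelial markers by a mean of 1.49 ± 0.22 on the log2 scale. This SE is over genes, which are not independent, and not over samples. On ob/ob replicates 1, 2 and 3 the medians were 0.86, 1.54 and 1.46 for macrophage markers and 0, -0.3 and -0.2 for endothelial markers. These medians argue against a lower share of adipocytes as the whole cause. The rise of macrophage markers does not rest on 1 array either, since the lowest ob/ob array had a median 0.77 above the highest ob/+ array. Whether the ob/ob samples held more macrophages or higher levels per macrophage was not tested.

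Calls of dim reporters may come from rounding of the intensities. Of 1647 such calls, 56.0% exceeded a limit that takes every rounding error as 0.005 upward, between the bounds set for and against rounding. Downward errors are larger on the log2 scale, so at most 56.0% exceed the largest error that rounding allows. Against a looser limit, the mean rounding error of 1 array's ratio, 90.3% exceeded it, so the share depends on the limit and rounding stays open.

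With 3 samples against 3 there are 10 splits, too few for a share under 0.05. The real split gave 8225 reporters and 6328 genes, and the highest other splits gave 13 and 9, so 1 of 10 splits was as large for each. For the gene lists the real split gave 16 and the highest other 24, so 2 of 10 splits were as large. Every other split mixes the genotypes, so a genotype difference widens the spread within its groups and lowers its counts of reporters and genes. Part of that difference also remains between its groups. The other splits therefore do not show what chance alone would give.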
